A study of Mus musculus with 24 samples.

How the data were processed

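Liver RNA of 24 samples was measured by total RNA sequencing, and the deposited table holds counts, whole numbers per Ensembl gene and library, without normalization. Per the labels' protocols, libraries were made from 250 ng of total RNA with a stranded kit after ribosomal RNA depletion, amplified for 12 cycles, pooled by 18 and sequenced as paired reads of 100 bases. Per the submitters' processing notes, the authors aligned reads with STAR 2.4.0i to the mouse build mm10. The counting tool, the annotation release, the strand setting, filters and the pool of each library are not given in the sources used here. Genes that overlap another gene on the opposite strand, such as Nr1d1 with Thra, Dbp with Sphk2, Rgs16 with Gm28513 and Igf2bp3 with Malsu1, are therefore uncertain to the extent that reads of the other strand were counted, and so are genes that share sequence with relatives. Raw reads were not analysed here. Gene positions were taken from GENCODE M21 (GRCm38), which may not be the annotation used for counting; 17256 of the 17275 tested genes had a position there.

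Samples were grouped by genotype and zeitgeber time as the labels give them, into 12 groups of 2. All columns were used, including 5 HepKO replicate 2 columns whose names carry a suffix that the labels do not explain. Total counts ran from 12997689 to 30677807 per library. PCR reads without molecular identifiers are not independent molecules, and the replicates of a group differed by 8.87 to 59.2 times the counting variance (chi-square per degree of freedom), so the spread between libraries and not the count alone set the precision.

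The models, thresholds, gene lists and rules for naming genes were chosen before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), the quasi-likelihood F test, and Benjamini-Hochberg adjusted p below 0.05 as the threshold, two-sided. A model with 1 level per group (12 residual degrees of freedom) gave the genotype difference averaged over the 6 times, the difference at each time, and the interaction of genotype with time. A model with a 24 h cosine and sine within each genotype (18 residual degrees of freedom) gave the rhythm in each genotype and the difference between rhythms; amplitude is the fitted distance from mean to peak in log2 units. Levels are given as CPM scaled by TMM, with the SD over the 12 libraries of a genotype, which includes the change over the day; fold differences are fitted values averaged on the log scale. Gene lists, 37 in all and 35 with at least 3 tested genes, were written from textbook knowledge and tested with camera at a preset correlation of 0.01, with a correlation estimated from the data, and with fry; enrichment in rhythm differences used Fisher's exact test, one-sided, against all tested genes. camera compares a list with other genes, whereas fry tests whether the genes of a list move, on balance, one way. The phase shift was the median difference of peak times over genes rhythmic in both genotypes, with a permutation of genotype labels within times (100 draws).

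Genes named were the core clock list; the 10 largest increases and decreases of the genotype difference among genes with a mean log2 CPM of at least 1 and the same sign at all 6 times; the 10 largest HepWT amplitudes with a lower and the 6 largest HepKO amplitudes with a higher amplitude in HepKO; the 10 largest mean amplitudes among genes rhythmic in both; the 2 increases and 2 decreases of smallest p at each time; and up to 4 genes of each list. The 8 predicted gene models and pseudogenes that this rule takes are left out of the text except for 2010003K11Rik and 3930402G23Rik. Afp, Afm, further genes of the HepWT replicates and the discussion of Alb were chosen after their values were seen.

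Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, other filters, a replicate block, a 12 h harmonic, a threshold of 0.01, single-genotype fits, model selection by the Bayesian information criterion among 5 models, and leaving out each library. Where that left a group with 1 library, the lone library was assumed to vary like the other groups. Added after the data were seen were fits without the 5 libraries of low depth, with HepWT replicate 1 or replicate 2 libraries alone, and with a block in HepWT only. That block gives HepWT replicate 2 a shift of its own, so the genotype difference compares HepKO with the level of HepWT replicate 1. For genotype differences it is therefore not separate evidence from the fit with HepWT replicate 1 alone. The methods were tested on simulated data: of 100 genes given a genotype difference of 0.5 (log2), 71% were called, and of 100 given a difference of 1, 97%; 96% of rhythms reduced from an amplitude of 1 to 0 and 52% of those reduced from 1 to 0.5 were called, with 2.89% and 2.63% false calls. The simulated counts were drawn independently for each library, without a difference shared by libraries of 1 replicate number. Only genes given a rhythm had one, and changes were placed only in genes with a mean of at least 1 CPM. The shares of true and false calls in the real data may therefore differ. No library was left out of the reported values. Some genes are not reported here.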

Results

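RNA was sequenced from mouse liver in which the clock gene Arntl (also called Bmal1) had been deleted in hepatocytes. Livers of mice that kept it were sequenced as well. Per the labels, HepKO mice carried floxed Arntl and a Cre recombinase transgene under the albumin promoter, while HepWT mice carried the floxed gene without Cre. All were C57BL/6 mice of 8 to 12 weeks that were fed at night. Livers were taken at zeitgeber times (ZT, hours after lights on) 2, 6, 10, 14, 18 and 22, with 2 libraries for each of the 12 combinations of genotype and time, which gives 24 libraries. Whether each library came from a separate animal is not given in the sources used here, so the p values measure only the spread between these samples. Total counts were 12997689 to 16910415 in the 5 HepKO replicate 2 libraries of ZT6, 10, 14, 18 and 22, and 23583035 to 30677807 in the other 19 libraries. Of 35304 genes in the table, 17275 had enough counts to be tested. The first principal component of these genes, with 21.4% of the variance, placed all 12 HepKO libraries below 0 and all 12 HepWT libraries above it. The replicate 2 libraries of HepWT differed from the replicate 1 libraries in 81 genes, among them higher collagen genes and Igf2bp3. The tests treated the 24 libraries as independent, so p values of genotype differences may be too small for genes with such a shared difference.

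The deleted gene was examined first, in every library. Arntl encodes a transcription factor that pairs with CLOCK or NPAS2 to drive the clock. It has the identifier ENSMUSG00000055116 and lies on chromosome 7 from 113207465 to 113314126 of GRCm38. In HepWT liver its level ran from 1.27 CPM (counts scaled to library size) at ZT10 to 46.0 CPM at ZT2, whereas all 12 HepKO libraries lay between 10.3 and 17.7 CPM. Its fitted 24 h amplitude was 2.27 ± 0.23 (log2, SE) in HepWT and 0.32 ± 0.20 in HepKO, and the 2 rhythms differed (adjusted p = 0.00208). The mean level over the day did not differ on the log scale, with a log2 difference of 0.04 ± 0.07 (adjusted p = 0.705), while the arithmetic means were 23.1 ± 17.7 CPM (SD, n = 12) in HepWT and 13.7 ± 2.38 CPM in HepKO. With time fitted as a 24 h wave the log2 difference was -0.14, and without HepWT ZT14 replicate 2 it was -0.01. The counts cover whole genes, so exons outside the floxed part and cells other than hepatocytes both count toward these levels.

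The rest of the clock stood apart between genotypes in 2 directions. Higher in HepKO averaged over the day were Npas2, the paralogue of Clock, by 19.8-fold (log2 4.30 ± 0.13, adjusted p = 2.22e-13), the repressor Cry1 by 3.26-fold, and Clock by 1.41-fold. Lower were the repressor Nr1d2 (REV-ERB beta) by 3.33-fold, Nr1d1 (REV-ERB alpha) by 3.25-fold, the repressors Ciart by 4.79-fold and Bhlhe41 by 7.87-fold, and the period gene Per3 by 1.61-fold. Per2 was higher on the log scale (log2 0.51 ± 0.08) although its arithmetic means were 41.7 CPM in HepWT and 40.4 CPM in HepKO. Arithmetic means of Npas2 were 2.95 CPM in HepWT and 20.4 CPM in HepKO, a smaller rise than the fitted one. The log2 difference of Npas2 ran from 1.31 at ZT22 to 7.13 at ZT10. Of the 15 core clock genes tested, 7 rose and 5 fell, the same counts as adjusted over the list alone, while Arntl, Per1 (log2 0.39) and Bhlhe40 (log2 0.11) did not pass. Per1 passed without HepKO ZT14 replicate 2 (0.48) or HepWT ZT18 replicate 2 (0.56). Cry2 rose by 1.23-fold, a call lost without the 5 HepKO libraries of low depth (0.29) and with a block in HepWT only (0.18). Rora, with a log2 difference of 0.16, lost its call without HepKO ZT14 replicate 2 (0.13), HepKO ZT18 replicate 1 (0.15), HepKO ZT22 replicate 1 (0.14), HepWT ZT14 replicate 2 (0.13), HepWT ZT18 replicate 1 (0.15) or HepWT ZT6 replicate 2 (0.13). Its call was also lost with time as a 24 h wave (0.14), without the 5 HepKO libraries of low depth (0.16), against HepWT replicate 1 alone (0.12) and with a block in HepWT only (0.11). As a list, the core clock was called higher (adjusted p = 0.0026; adjusted p = 0.21 with an estimated correlation), with a median log2 difference of 0.16 and a mean of -0.01. With HepWT replicate 1 libraries alone, an alternative added after the data were seen, the adjusted p of the list was 0.134, and with a block in HepWT only, also added then, it was 0.138. Within HepWT the list was lower in replicate 2 by a median log2 of -0.08 (adjusted p = 0.0142; 0.32 with an estimated correlation).

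**Figure D1:**
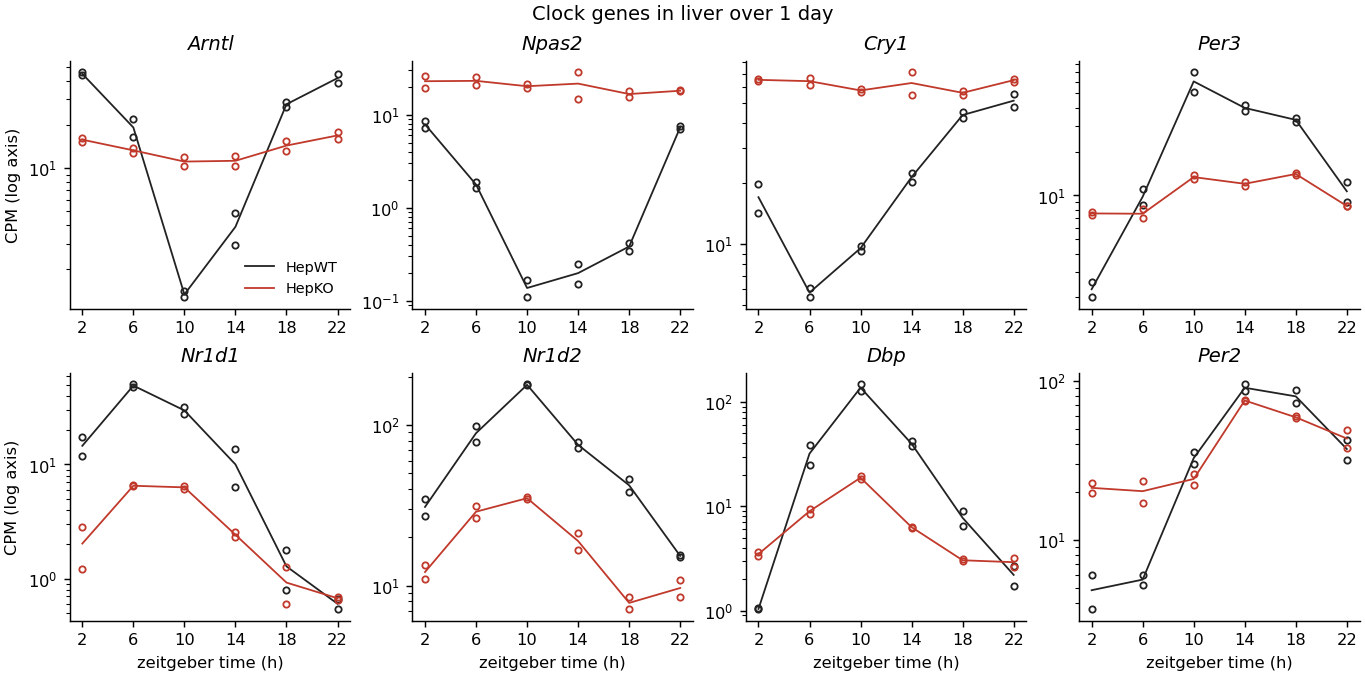
Level (CPM, log axis) of 8 clock genes against zeitgeber time (h) in HepWT (black) and HepKO (red). Open points are the 2 libraries of each group and lines join their means. Arntl stays between 10.3 and 17.7 CPM in HepKO while it spans 1.27 to 46.0 CPM in HepWT.

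Averaged over the day, the genotypes differed in 4572 of the 17275 genes, 2278 higher and 2294 lower in HepKO. Differences of at least 2-fold were held by 316 of the higher and 336 of the lower genes, and the sign was the same at all 6 times in 1582 higher and 1552 lower genes. Without the 5 HepKO libraries of low depth, an alternative added after the data were seen, 2886 genes were called (1490 higher, 1396 lower). With HepWT replicate 1 libraries alone 3621 were called, and with replicate 2 alone 4182.

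Some of the genes that rose most in HepKO had means below 1 CPM in HepWT. Moxd1, a copper monooxygenase, went from 0.268 ± 0.292 CPM (SD, n = 12) to 142 ± 122 CPM, and Sult1e1, the oestrogen sulfotransferase, from 0.125 to 13.6 ± 23.5 CPM, where HepKO ZT14 replicate 1 alone held 80.2 CPM. Ntrk2, the receptor of brain-derived neurotrophic factor, rose from 0.760 to 27.5 CPM (log2 5.30 ± 0.31, adjusted p = 1.46e-09). Slc34a2, a sodium-dependent phosphate transporter, rose by 14.4-fold, Cyp2c55, a cytochrome P450, by 11.7-fold, the muscarinic receptor Chrm3 by 11.4-fold and Loxl4, a lysyl oxidase of the extracellular matrix, by 11.3-fold. Grk5, a kinase of G protein-coupled receptors on chromosome 19 from 60889749 to 61095968, rose by 9.40-fold (log2 3.23 ± 0.06, adjusted p = 1.03e-16) and was among the genes with the smallest p at every time.

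Several of the genes that fell most were close to absent from HepKO liver. Rgs16, a regulator of G protein signalling, had 15 counts in the 12 HepKO libraries and a mean of 12.3 ± 20.5 CPM (SD, n = 12) in HepWT. Cyp17a1, a cytochrome P450 of steroid synthesis, fell from 6.91 to 0.721 CPM, the trefoil peptide Tff3 from 6.10 to 0.247 CPM, the peroxisomal thioesterase Acot3 from 6.17 to 0.303 CPM and the membrane peptidase Mme (neprilysin), still present, from 42.2 ± 15.8 to 4.98 ± 1.89 CPM. Igf2bp3, an RNA-binding protein of fetal tissue, had 10 counts in HepKO, but its HepWT mean of 4.33 CPM came mainly from the replicate 2 libraries, with 8.22 CPM there and 0.432 CPM in replicate 1. Its log2 difference of -6.91 (adjusted p = 0.000768) was no longer called without HepWT ZT14 replicate 2 (-5.36), without HepWT ZT18 replicate 2 (-5.99), with limma-voom (-4.93) or against HepWT replicate 1 alone (-2.43). Cyp2a4, a P450 of steroid hydroxylation with 34 counts in HepKO (log2 -5.12), lost its call with limma-voom (-4.05), and the helix-loop-helix factor Tcf24 went from -3.81 to -1.99 against HepWT replicate 1 alone. Mup15, a major urinary protein, fell by 9.33-fold, to 42.0 ± 88.6 CPM (SD, n = 12) in HepKO, where ZT14 replicate 1 alone held 299.7 CPM, but lost its call against HepWT replicate 2 alone (-2.34). Reads of Cyp2a4, Mup15, the Gstm and Ugt1a genes and the pseudogenes can be shared with close relatives, so these values are less certain. 

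Lipid genes moved in opposite blocks. Of the 26 genes of cholesterol synthesis and uptake, 21 rose and 5 did not pass (21 rises and 1 fall adjusted over the list alone). Hmgcs1, an early enzyme of the pathway, rose by 3.26-fold (333 to 1014 CPM), Idi1 by 2.46-fold, Fdps by 2.15-fold and Insig2, which retains the sterol sensor in the endoplasmic reticulum, by 2.30-fold. The list test called it higher, with a median log2 difference of 0.79 (adjusted p = 4.29e-24; adjusted p = 0.107 with an estimated correlation). Of 36 PPARA targets and fatty acid oxidation genes, 25 fell and 1 rose (26 falls and 2 rises adjusted over the list alone), with Cpt1a, the entry step of mitochondrial oxidation, down by 1.60-fold, the peroxisomal thiolase Acaa1a by 1.70-fold, and the fatty acid carrier Fabp1 from 3103 to 1840 CPM. Their median log2 difference was -0.40 (adjusted p = 1.34e-13; adjusted p = 0.21 with an estimated correlation). Of 24 genes of fatty acid and triglyceride synthesis, 13 fell and 2 rose (16 and 2 adjusted over the list alone): the desaturase Fads2 fell by 1.85-fold and the lipogenic factor Thrsp by 1.92-fold, whereas the elongase Elovl3 rose by 6.61-fold. That list had a median log2 difference of -0.42 (adjusted p = 0.00316; adjusted p = 0.789 with an estimated correlation) and an adjusted p of 0.336 against HepWT replicate 2 alone. Within HepWT, replicate 2 libraries were lower than replicate 1 in the medians of the last 2 lists, by log2 -0.15 and -0.20.

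Camera also called lists of detoxification, ribosomal protein, pericentral and oxidative phosphorylation genes. Of 40 genes of xenobiotic metabolism, 15 rose and 14 fell (15 and 17 adjusted over the list alone). The glutathione transferases Gstm2 and Gstm3 rose by 5.85-fold and 6.84-fold and Gstm1 by 1.27 (log2), while the sulfotransferase Sult1a1 fell by 2.65-fold and the carboxylesterase Ces1d by 3.18-fold. This list was called higher with a mean log2 difference of 0.14 but a median below 0 (adjusted p = 0.0455; adjusted p = 0.789 with an estimated correlation). The call was lost without HepKO ZT10 replicate 2 or any 1 of the 12 HepWT libraries (adjusted p from 0.057 to 0.329), against HepWT replicate 1 alone (adjusted p = 0.808) and with a block in HepWT only (0.755). Within HepWT its median was lower in replicate 2 by log2 -0.10 (adjusted p = 0.00144; 0.296 with an estimated correlation). Of 78 ribosomal protein genes, 58 rose (65 adjusted over the list alone) by small amounts, such as Rpl17 by 1.23-fold and Rps12 by 1.30-fold, with a median log2 difference of 0.18 (adjusted p = 2.18e-10; adjusted p = 0.789 with an estimated correlation), beside a median of -0.12 in HepWT replicate 2 against replicate 1. Of 20 pericentral hepatocyte genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone), including Oat (ornithine aminotransferase) by 2.93-fold and Lhpp by 2.13-fold (adjusted p = 0.0026; adjusted p = 0.789 with an estimated correlation). Of 44 oxidative phosphorylation genes, 13 fell (15 falls and 1 rise adjusted over the list alone), with Sdhd down by 1.28-fold and a median log2 difference of -0.07 (adjusted p = 0.0276; adjusted p = 0.803 with an estimated correlation). Their call was lost without HepKO ZT10 replicate 1, HepWT ZT18 replicate 1, HepWT ZT22 replicate 1 or HepWT ZT6 replicate 1 (adjusted p from 0.0600 to 0.0789), without the 5 libraries of low depth (0.0719) and against HepWT replicate 2 alone (0.450). Replicate 2 of HepWT was lower than replicate 1 in their median by log2 -0.06 (adjusted p = 0.0012; 0.557 with an estimated correlation), close in size to the genotype median.

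Several lists were lower in HepKO and, in the HepWT libraries, higher in replicate 2 than in replicate 1. Of 26 female-biased liver genes, 14 fell and 5 rose, the same counts as adjusted over the list alone: Fmo1 fell by 1.76-fold, while Lpl, which releases fatty acids from lipoproteins, rose by 9.13-fold. Their median log2 difference was -0.78 (adjusted p = 0.0258; adjusted p = 0.789 with an estimated correlation), beside 0.54 for HepWT replicate 2 against 1. The call was lost without any 1 of the 12 HepKO libraries (adjusted p from 0.057 to 0.152), without the 5 of low depth (0.202), against HepWT replicate 1 alone (0.279) and with a block in HepWT only (0.237). Of 27 interferon response genes 10 fell (11 adjusted over the list alone), such as the guanylate-binding protein Gbp7 by 1.39-fold and Igtp by 1.57-fold, with a median of -0.24 (adjusted p = 0.00374; adjusted p = 0.794 with an estimated correlation), beside 0.41 between the HepWT replicates and an adjusted p of 0.455 against replicate 1 alone and 0.483 with a block in HepWT only. Of 29 cell cycle genes 15 fell and 3 rose (17 and 3 adjusted over the list alone): Rrm2, a subunit of ribonucleotide reductase, fell by 2.53-fold and Ccnb2 (cyclin B) by 2.70-fold, whereas the helicase subunit Mcm4 rose by 1.58-fold. Their median was -0.75 (adjusted p = 0.0312; adjusted p = 0.803 with an estimated correlation), beside 0.88 between the HepWT replicates. Against HepWT replicate 1 alone (adjusted p = 0.336) and with a block in HepWT only (0.755) the direction of the cell cycle list reversed, and its call was lost without HepKO ZT10 replicate 1 (0.0600), HepWT ZT18 replicate 2 (0.182), HepWT ZT22 replicate 2 (0.214) or HepWT ZT2 replicate 2 (0.0926).

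Among the lists of cell type markers, camera called only the Kupffer cell and macrophage list. Fry also called hepatocytes, a list that holds Alb, lower (adjusted p = 0.0176). It called liver endothelium (0.00324) and T and NK cells (0.0245) lower and cholangiocytes (0.0401) higher. Of the 17 Kupffer cell genes 13 fell (15 adjusted over the list alone) and Mpeg1 rose by 1.63-fold. The complement genes C1qa and C1qb fell by 1.32-fold and 1.36-fold and the secreted factor Cd5l by 1.38-fold, with a list median of -0.37 (adjusted p = 0.0026; adjusted p = 0.789 with an estimated correlation). Within HepWT this list was higher in replicate 2 by a median log2 of 0.23, and its adjusted p was 0.134 against replicate 1 alone and 0.0755 with a block in HepWT only. With camera the adjusted p was 0.42 for hepatocytes, and no call was made for liver endothelium (0.135), stellate cells and fibroblasts (0.169), cholangiocytes (0.356), T and NK cells (0.221), B and plasma cells (0.732), neutrophils (0.85), erythroid cells (0.195) or adipocytes (0.409), and the exocrine pancreas list had only 2 genes tested. Single markers moved within these lists: the cholangiocyte genes Sox9 and Spp1 rose by 2.30-fold and 2.08-fold, and the collagen gene Col3a1 fell by 2.21-fold, with 62.0 CPM in HepWT replicate 1, 141 CPM in HepWT replicate 2 and 46.7 CPM in HepKO, so that replicate 2 carried most of the difference. Alb (albumin), on chromosome 5 from 90460897 to 90476602, fell from 63920 ± 7972 CPM to 25010 ± 4309 CPM (SD, n = 12; log2 -1.36 ± 0.09, adjusted p = 4.31e-09), with no overlap between the genotypes.

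The other lists held calls in single genes without a call by camera. Fry nevertheless called bile acids higher (adjusted p = 0.00446) and glycolysis and glycogen lower (0.0339). Adjusted p values by camera were 0.0616 for glycolysis and glycogen, where the glycogen synthase Gys2 fell by 2.36-fold, and 0.0616 for acute phase genes. They were 0.135 for male-biased genes, 0.165 for ribosome biogenesis, 0.262 for heat shock, 0.425 for periportal hepatocytes, 0.409 for bile acids, where the coreceptor Klb fell by 1.55-fold, and 0.409 for endoplasmic reticulum stress, where Asns (asparagine synthetase) fell by 4.40-fold and the list median was above 0 with a mean below it. They were 0.536 for NRF2 and glutathione, 0.71 for growth hormone signalling, 0.808 for iron and heme, 0.85 for cell cycle inhibitors, where Cdkn1a (p21) rose by 5.30-fold, and 0.85 for gluconeogenesis, where Agxt rose by 1.83-fold. The cold-inducible list had 2 genes, of which Rbm3 rose by 0.14 (log2). Clock output factors with PAR bZIP proteins, among the lists called, had 7 falls and 3 rises of 13, the same as adjusted over the list alone: Dbp fell by 2.13-fold, the cytochrome P450 reductase Por by 2.16-fold and Nampt, which makes the NAD precursor, by 1.62-fold (list adjusted p = 0.00658; adjusted p = 0.107 with an estimated correlation; 0.0658 against HepWT replicate 2 alone). Arithmetic means of Dbp were 36.6 CPM in HepWT and 7.26 CPM in HepKO, a larger fall than the fitted one. All 13 list calls were lost with an estimated correlation. With a filter at a mean of 1 CPM the xenobiotic (adjusted p = 0.0987), female-biased (0.0807) and cell cycle (0.125) lists lost theirs. The rotation test fry called 18 lists, without the cell cycle list (adjusted p = 0.183).

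**Figure D2:**
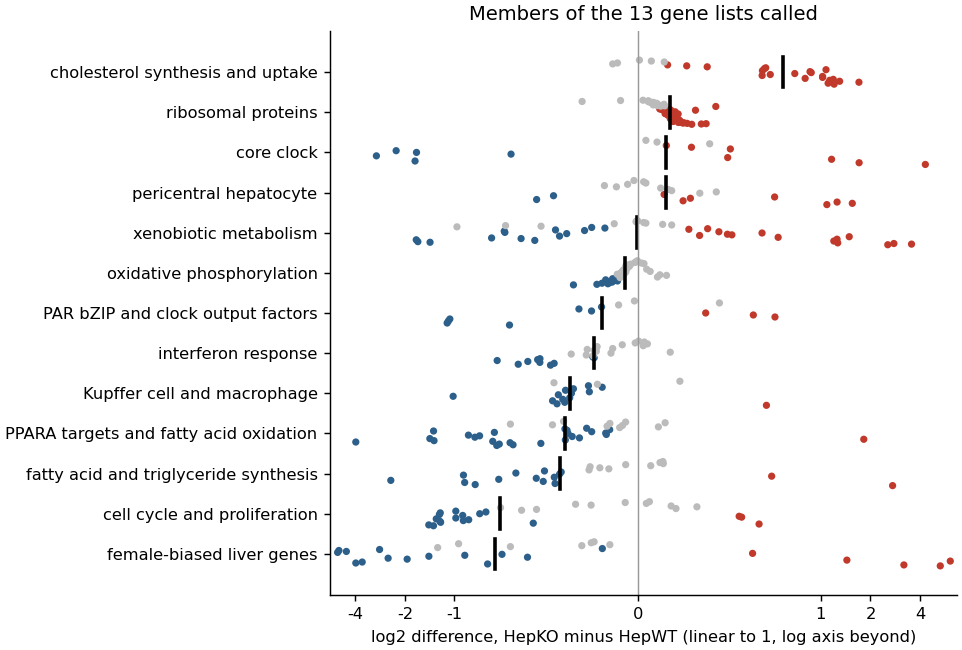
Log2 difference (HepKO minus HepWT; linear to 1, log axis beyond) of each tested gene of the 13 lists called by camera. Red points rose, blue points fell, grey points did not pass, and black bars are list medians. Cholesterol genes lie mostly above 0 with a median of 0.79 and PPARA targets mostly below 0 with a median of -0.40.

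At single times, each with 2 libraries against 2, the number of genes called was 321 at ZT2, 857 at ZT6, 1332 at ZT10, 1320 at ZT14, 654 at ZT18 and 233 at ZT22. Grk5 was among the top increases at all 6 times, from a log2 difference of 2.49 ± 0.13 at ZT2 to 3.71 ± 0.14 at ZT10. Cry1 joined it at ZT2 (1.93) and ZT6 (3.47), Clpx, a chaperone of the mitochondrial matrix, at ZT10 (2.75) and ZT14 (2.45), Loxl4 at ZT18 (4.63) and the glutathione transferase Gstm6 at ZT22 (1.97). The top decreases were Ugt1a9, a glucuronosyltransferase, and the class I gene H2-Q7 at ZT2 (-3.37 and -1.58), Nr1d2 at ZT6, ZT10 and ZT18 (-1.63, -2.34 and -2.42), the output factor Dbp at ZT10 (-2.87), and Nampt and the lipase Abhd6 at ZT14 (-1.83 and -2.07). The guanine deaminase Gda followed at ZT18 (-1.63), and Hsd11b1, which regenerates active glucocorticoid, and Kalrn at ZT22 (-0.89 and -0.73). At ZT2, Dbp (1.74, adjusted p = 0.00154) and Per3 (1.72, adjusted p = 7.07e-05) were higher in HepKO, opposite to their averages over the day. A test that the genotype difference was equal at all times was rejected for 193 genes.

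These single-time counts rest on few libraries. Without HepKO replicate 1 or 2 of the time itself they were 91 and 107 at ZT2, 286 and 200 at ZT6, 551 and 651 at ZT10, 244 and 284 at ZT18, and 108 and 131 at ZT22. Without HepWT replicate 1 or 2 they were 368 and 563 at ZT6, 631 and 669 at ZT10, 393 and 278 at ZT18, and 136 and 125 at ZT22; they were 80 without HepWT ZT2 replicate 2 and 844 without HepWT ZT14 replicate 1. Without the 5 libraries of low depth the counts were 165, 137, 488, 612, 187 and 80 from ZT2 to ZT22, and 43 genes differed between times.

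**Figure D3:**
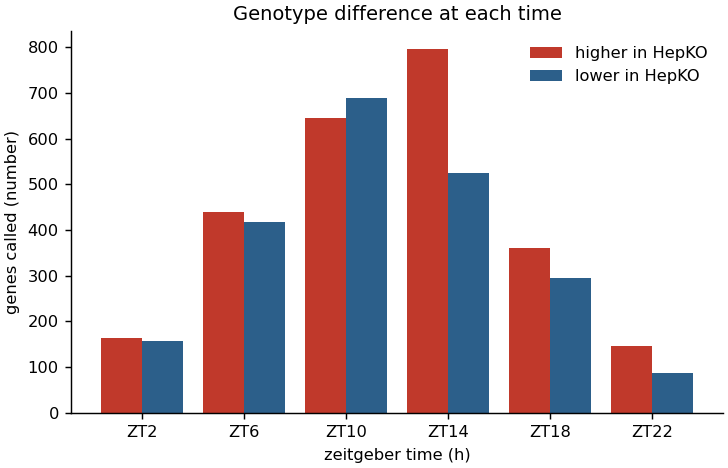
Number of genes called higher (red) or lower (blue) in HepKO at each zeitgeber time, with 2 libraries per genotype. At ZT14, 795 genes were higher and 525 lower, and at ZT22, 145 were higher and 88 lower.

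The daily rhythms of many genes were weaker in HepKO. A 24 h rhythm was called for 5239 genes in HepWT and 2471 in HepKO, and for 1803 in both, where independent lists would share 749.4. A rhythm called in 1 genotype and not in the other is not a difference in itself, so the difference was tested directly: 259 genes changed their rhythm, 245 with a lower and 14 with a higher fitted amplitude in HepKO, and 2155 had an unadjusted p below 0.05. The test covers amplitude and peak time together. Npas2 lost most of its wave (amplitude 3.38 ± 0.18 to 0.20 ± 0.11, log2, SE; adjusted p = 1.54e-08), as did Cry1 (1.54 to 0.08), Clpx (1.36 to 0.14) and Clock (0.57 to 0.07). Dbp kept a smaller wave (3.26 to 1.38), as did Per2 (2.27 to 1.02) and Loxl4 (1.90 to 0.57). Amplitudes were also lower for Per3 (2.04 to 0.49), Slc34a2 (2.36 to 0.52), the tubulin gene Tubb2a (2.04 to 0.54), the cell cycle inhibitor Cdkn1a (2.03 to 0.75), Nampt (1.103 to 0.282), Grk5 (1.11 to 0.56) and Gda (0.62 to 0.34). Amplitudes of Nr1d1 (2.88 to 1.72, adjusted p = 0.189), Nr1d2 (difference -0.47, adjusted p = 0.0527) and Ciart (3.31 to 2.02, adjusted p = 0.547) did not pass the test of a difference. Without HepWT ZT10 replicate 2 the call of Clock was lost (amplitude difference -0.45). Against HepWT replicate 2 alone those of Clock (-0.44) and Per3 (-1.52) were lost. Nr1d2 was called with DESeq2 (-0.474), a filter at a mean of 1 CPM (-0.462), no filter (-0.464) and a block in HepWT only (-0.466). With a 12 h harmonic added (-1.397), without a filter (-1.162) and against HepWT replicate 2 alone (-1.48) Nr1d1 was called. Ciart was called without a filter (-1.285). Nr1d1 was called without HepWT ZT14 replicate 1 (-1.27), and Nr1d2 without HepKO ZT2 replicate 1 (-0.47), HepWT ZT14 replicate 1 (-0.49), HepWT ZT14 replicate 2 (-0.51), HepWT ZT18 replicate 1 (-0.52) or HepWT ZT2 replicate 1 (-0.49).

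**Figure D4:**
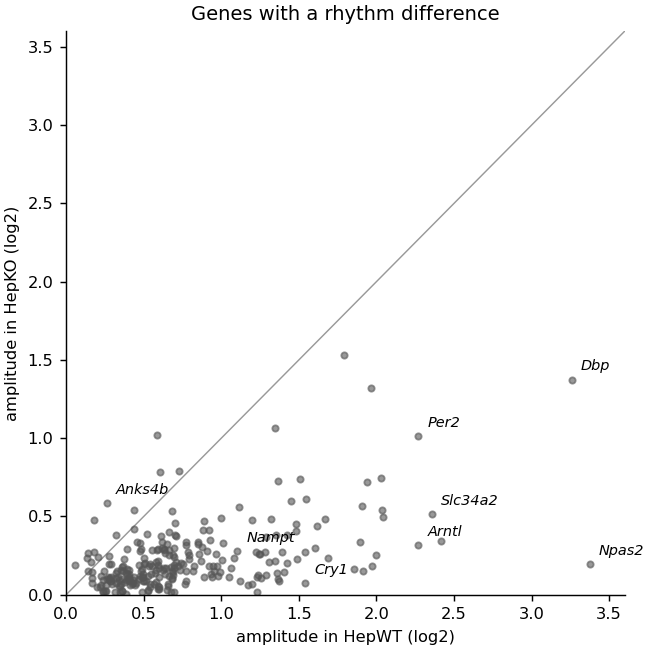
Fitted 24 h amplitude (log2) in HepKO against HepWT of the 259 genes with a rhythm difference. The line marks equal amplitudes; 245 points lie below it and 14 above.

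Of the 15 core clock genes, 7 had a rhythm difference (12 adjusted over the list alone), and of the 13 output factors, 6 (11 adjusted over the list alone). These were the 2 lists enriched in rhythm differences, with adjusted p of 3.19e-08 and 2.94e-07 by Fisher's exact test. There were 4 lists enriched without HepWT ZT22 replicate 2 or without HepWT ZT6 replicate 2. The few genes with a higher fitted amplitude in HepKO included Anks4b (0.26 to 0.59), the aspartate oxidase Ddo (0.44 to 0.54), Azin1, an inhibitor of antizyme (0.32 to 0.38), Haus8 (0.18 to 0.48), Eml3 (0.18 to 0.27) and 2010003K11Rik (0.60 to 0.78), whose difference was -0.01 without HepKO ZT18 replicate 1. Their peaks moved as well, by 3.44 h (Anks4b), 3.01 h (Ddo), 5.21 h (Azin1), -8.48 h (Haus8), 7.39 h (Eml3) and 8.79 h (2010003K11Rik). The amplitude differences of Ddo (0.10 ± 0.09, SE), Azin1 (0.06 ± 0.09), Eml3 (0.09 ± 0.07) and 2010003K11Rik (0.18 ± 0.23) were less than 2 SE from 0, so a gain in amplitude was not shown for them. Single libraries ended these calls: 12 of the 24 for Anks4b and for Ddo, 13 for Azin1 and 18 for Haus8, with amplitude differences from 0.02 to 0.35. The count of 14 itself ran from 5 (without HepKO ZT10 replicate 1 or HepWT ZT14 replicate 1) to 25 (without HepKO ZT22 replicate 2), and the total of 259 was 171 without HepKO ZT2 replicate 1. Without the 5 libraries of low depth, 173 genes had a rhythm in HepKO and 66 a rhythm difference, all 66 with a lower amplitude, and the calls of Arntl, Clock, Dbp, Per2 and Per3 were lost at amplitude differences of -1.96, -0.54, -1.94, -1.21 and -1.56.

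A set of genes cycled in both genotypes. Of the 1803 genes with a rhythm in both, 1453 had an unadjusted p of 0.05 or more for a difference, which does not show that their rhythms are equal. Those with the largest amplitudes included the immediate early gene Egr1 (2.46 in HepWT and 2.25 in HepKO, log2), Noct (2.05 and 1.33) and the feeding-induced lipase inhibitor Angptl8 (1.58 and 1.71). They also included the lysolipid transporter Mfsd2a (1.76 and 1.49), the lipolysis inhibitor G0s2 (1.20 and 1.62) and the heat shock gene Hspa1b (1.65 and 1.44). The receptor subunit Chrna4 (1.497 and 1.560) and the zinc finger gene Zfp9 (1.49 and 1.30) were among them as well. The heat shock list had 20 of 22 genes rhythmic in HepWT and 18 in HepKO, with 0 rhythm differences by edgeR over all genes, 0 over the list alone and 0 at an unadjusted p below 0.05. Over the 1803 genes the peak in HepKO came at a median of -0.27 h relative to HepWT (quartiles -1.37 and 0.855 h), and 1348 genes (74.8%) peaked within 2 h. A permutation of genotype labels within times gave p = 0.39, 2-sided. The median was 0.06 h without HepKO ZT14 replicate 1, 0.002 h without HepWT ZT10 replicate 1 and 0.44 h against HepWT replicate 2 alone.

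**Figure D5:**
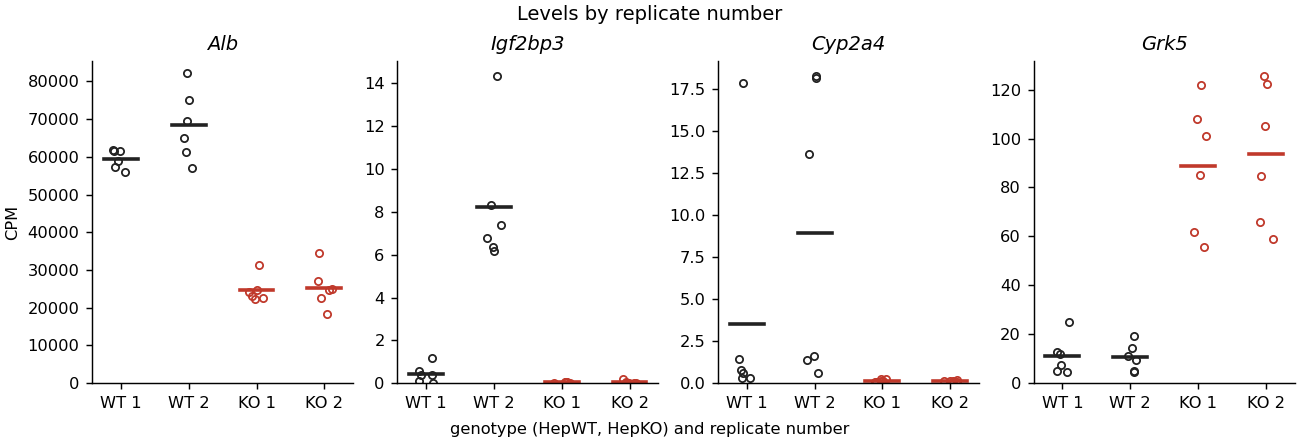
Level (CPM) of 4 genes in each library, by genotype and replicate number, with bars at the means of 6 libraries. Igf2bp3 averages 8.22 CPM in HepWT replicate 2 and 0.432 CPM in HepWT replicate 1, and Alb lies between 55920 and 82220 CPM in HepWT and between 18420 and 34520 CPM in HepKO.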

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

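The test of the spread between libraries was chosen only after the result was seen; the other tests of this part were fixed beforehand.

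Several of the genes named had a genotype difference that was not equal at the 6 times by the interaction test. The smallest adjusted p values were those of Clpx (2.42e-08), Arntl (1.30e-07) and Cry1 (2.70e-07), followed by Npas2, Per3 and Dbp (8.73e-07 each), Nampt (1.99e-06), Loxl4 (5.56e-06) and Per2 (5.35e-05). The others were Slc34a2 (0.00128), Grk5 (0.00217), Bhlhe40 (0.00264), Nr1d2 (0.00294), Clock (0.00351), Abhd6 (0.00833), Gda (0.0171), Per1 (0.0272) and 3930402G23Rik (0.0492). Arntl was lower in HepKO at ZT2 (log2 -1.51) and higher at ZT10 (3.05), and Grk5 was higher at every time, by 2.49 to 3.71.

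Libraries were regrouped at random within each time in 100 splits, the real one included. The genotype difference of 4572 genes was reached by 1 split, the real one, against 2850 in the highest other, which differed from the real split by 1 exchange of libraries. The rhythm difference of 259 genes was likewise reached by 1 split (highest other 115), and the gap of 2768 between the numbers of rhythmic genes by 1 split (highest other 2007), so chance can be excluded for these results. For the interaction, 3 splits, the real one included, called at least 193 genes, and the others among them called 208 and 669. Few splits reached the real count, but random regrouping could exceed it, so chance cannot be excluded there. For the 13 gene lists, 27 splits called as many (highest other 20), so chance cannot be excluded for their number. For the 2 lists enriched in rhythm differences, 3 splits, the real one included, gave at least as many (highest other 3). Few splits reached this number, but chance cannot be excluded for it. For the phase shift of 0.266 h in size 39 splits gave as large a value (highest other 0.771 h), so chance cannot be excluded.

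The lower number of rhythmic genes in HepKO was weighed against sequencing depth and spread. With every library thinned to 12997689 counts, 4467 genes were rhythmic in HepWT and 2080 in HepKO, a ratio of 2.15, close to the 2.12 of the full data, which argues against depth. The spread within groups was smaller in HepKO, with a median SD ratio of 0.925, and fits to the 12 libraries of each genotype alone still gave 3876 against 2723 genes, a ratio of 1.42, which argues against a larger spread. A weaker clock output after loss of Arntl is a candidate explanation, as a hypothesis that was found on these data and not tested on others. With 1 library per group, a fit added after the data were seen, the rhythmic genes numbered 1303 in HepWT and 15 in HepKO for replicate 1, and 1301 and 1 for replicate 2.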

How the results depend on the processing

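Alternatives with the 5 low-depth libraries left out, with HepWT replicate 1 or 2 alone and with a block in HepWT only were chosen after the data were seen. The others were planned. Of 1083 values of named genes and lists under alternatives other than leaving out 1 library, 986 kept their direction and side of the threshold, 75 lost and 14 gained a call and 8 reversed. With 1 library left out, 2338 of 2472 were kept, 113 lost and 10 gained a call and 11 reversed. Replicate numbers did not pair the libraries across genotypes: deviations from group means correlated above 0.1 in 11 of 15 pairs of HepWT groups, in 1 of 36 pairs across genotypes and in none of the HepKO pairs. HepWT libraries of 1 replicate number thus shared deviations, while the tests treated them as independent. For genes with a shared deviation, the precision of the genotype difference is overstated. A replicate block gave 4597 genes for the genotype difference, 259 for the rhythm difference and 199 for the interaction. Unless the construction shows it, the cause was not tested.

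Without a filter on low counts the counts were 1246 at ZT2, 1691 at ZT6, 2030 at ZT10, 1314 at ZT18 and 1000 at ZT22, with 3844 at any time, 1655 for the interaction, 1367 for the rhythm difference (1076 lower, 291 higher amplitude), a phase shift of -0.551 h and 23 lists enriched in rhythm differences; the cause was not tested. DESeq2 gave 548 at ZT2, 451 at ZT22, 526 for the interaction and 574 rhythm differences (520 lower, 54 higher); the cause was not tested. The stricter threshold of 0.01 by construction gave fewer genes: 2928 (1493 higher, 1435 lower), rhythms of 3064 in HepWT and 888 in HepKO, 116 rhythm differences (114 lower, 2 higher) and a phase shift of -0.0232 h. Model selection called 4720 rhythm differences, without control of false calls. With an estimated correlation camera called 0 lists, while the preset called 13 and fry 18. Time as a 24 h wave gave an Arntl difference of -0.144; the cause was not tested.

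Without the 5 low-depth libraries, which leaves 7 of 12 HepKO libraries, the counts were 2886 (1490 higher, 1396 lower), 165, 137, 488, 612, 187 and 80 from ZT2 to ZT22, 902 at any time, 43 for the interaction, 173 rhythms in HepKO and 66 rhythm differences (66 lower and, with edgeR, 0 higher). Against HepWT replicate 1 alone they were 188 at ZT2, 8 lists, 2269 rhythms in HepWT, 165 rhythm differences (1 higher), a shift of -0.658 h and 5 enriched lists. Against HepWT replicate 2 alone they were 867 at ZT2, 380 at ZT22, 2640 rhythms in HepWT, 149 rhythm differences (145 lower, 4 higher), a shift of 0.440 h and 4 enriched lists. Fewer libraries per fit were part of these by construction, and the cause was not tested further. A block in HepWT only, with all 24 libraries, left 8 lists. By construction it compares HepKO with the level of HepWT replicate 1, so it largely repeats the fit against HepWT replicate 1 alone.

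Reversals were few, and the cause was not tested. The amplitude difference of Bhlhe41, not called, was 0.10 with DESeq2, 0.12 against HepWT replicate 1 and 0.14 with 2 harmonics; that of Azin1 was -0.0250 against HepWT replicate 2. The Afp difference was 0.33 against HepWT replicate 1 and 0.28 with the HepWT block, and the cell cycle list reversed in both (adjusted p = 0.336 and 0.755). With 1 library left out, the amplitude difference ran from -0.407 to 0.194 for Bhlhe41 and from -0.00940 to 0.277 for 2010003K11Rik, and the Afp difference from -0.308 to 0.107.

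Leaving out 1 library at a time gave these ranges: genotype difference 4094 to 4569 (2050 to 2335 higher, 2013 to 2283 lower). Those at single times were ZT2 80 to 453, ZT6 200 to 954, ZT10 551 to 1416, ZT14 844 to 1366, ZT18 244 to 716, ZT22 108 to 285 and any time 1849 to 2620. Those of the others were interaction 138 to 239, Arntl -0.0106 to 0.123, lists 10 to 15, rhythms 4376 to 5311 in HepWT and 1656 to 2584 in HepKO, rhythm difference 171 to 301 (162 to 285 lower, 5 to 25 higher), shift -0.494 to 0.0606 h and enriched lists 2 to 4. Depth limits genes near the floor, such as Rgs16 with 15 and Igf2bp3 with 10 counts in HepKO.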

Other observations

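The tests of fewer hepatocytes and of the neighbourhood of Alb, like the genes named in this part, were chosen only after the result was seen, as were the fits with HepWT replicate 1 or 2 alone.

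Some chaperones, ribosome assembly factors and cold-inducible genes had daily rhythms in both genotypes. The cochaperones Fkbp4 (amplitude 0.63 in HepWT and 0.52 in HepKO, log2) and Stip1 (0.71 and 0.59) peaked near ZT19, at 19.6 h and 19.1 h in HepWT and at 19.9 h and 19.4 h in HepKO. The nucleolar factors Nolc1 (1.00 and 0.76) and Rrp12 (0.96 and 0.63) peaked at 17.8 h and 17.5 h in HepWT and at 17.3 h and 17.0 h in HepKO, and of 26 ribosome biogenesis genes 21 were rhythmic in HepWT and 13 in HepKO. The cold-inducible RNA-binding protein gene Cirbp (0.85 and 0.72) peaked at 6.14 h and 6.85 h, and Rbm3 (0.39 and 0.35) at 13.6 h and 12.5 h. The endoplasmic reticulum chaperone Hyou1 had an amplitude of 0.72 in both genotypes.

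Alb fell to 25010 CPM, and of the other 20 most abundant genes 6 fell, with Serpina1e (an alpha-1 antitrypsin, log2 -1.05) the lowest, and 2 rose, Cyp3a11 (0.44) and the complement gene C3 (0.22). The neighbours Afm (log2 -0.22) and Afp (-0.10, adjusted p = 0.797) changed less or did not pass. The call of Afm was lost against HepWT replicate 1 alone (-0.13) and with a block in HepWT only (-0.13). The sign of Afp turned in both fits (0.33 and 0.28), as it did without HepWT ZT22 replicate 2 (0.04) or HepWT ZT2 replicate 2 (0.11). The lower Alb was weighed against scaling, cell number and its surroundings, with -0.68 as the bound (log2, a fall of the same kind at reduced size). The other 20 most abundant genes had a median of -0.0375 ± 0.108 (SE), the 19 other hepatocyte markers a median of -0.0167 ± 0.0825, and the 19 tested genes within 1 Mb of Alb a median of -0.1 ± 0.107, which argues against scaling by abundant genes, against fewer hepatocytes and against a change of the whole neighbourhood. The Cre transgene with the albumin promoter cannot be told apart from the deletion, since 0 HepWT libraries and all 12 HepKO libraries carry Cre per the labels. An effect of the transgene or of the deletion may each account for the lower Alb.

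Within HepWT, the replicate 2 libraries differed from the replicate 1 libraries in 81 genes, 48 higher and 33 lower. In HepKO edgeR called 0, with 493 at an unadjusted p below 0.05 against 2423 in HepWT. Higher in replicate 2 were the collagens Col3a1 (62.0 to 141 CPM) and Col1a1 (log2 1.22), elastin (Eln, 2.24 to 6.47 CPM), Igf2bp3 (0.432 to 8.22 CPM) and the P450 genes Cyp2b9 (0.143 to 5.95 CPM) and Cyp2c40 (log2 1.93), whereas the urinary protein gene Mup21 (182 to 62.0 CPM) was lower. Interferon response genes such as Usp18 (8.37 to 15.5 CPM) and Mx1 (2.31 to 3.7 CPM) were higher in replicate 2 as well. By camera their list was higher there (adjusted p = 4.99e-25, and 0.219 with an estimated correlation). Of the 81 genes, 46 were also called in the genotype difference, 23 of them higher in replicate 2 and lower in HepKO and 14 lower in replicate 2 and higher in HepKO. Over all tested genes, 26.47% were called in the genotype difference. The same replicate 2 libraries enter the HepWT mean of that difference, so part of this overlap arises by construction. Xist had at most 5 counts and the Y-linked Ddx3y at least 1564 counts in any of the 24 libraries.

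These HepWT libraries were weighed against depth, maturity and cell mixture. With all HepWT libraries thinned to 23583035 counts 90 genes were called, 78 of them among the 81, which argues against depth. Imprinted growth genes, which fall after birth, were higher in replicate 2 (camera p = 0.0276 with an estimated correlation). Of 13 tested genes 10 lay above 0, with a median log2 of 0.13, and only Peg3 passed singly (adjusted p = 0.0432 by edgeR). In the same camera setting, unadjusted p was 0.00631 for the interferon, 0.019 for the stellate and 0.0205 for the female-biased list. These lists were also higher in replicate 2, each with an adjusted p of 0.219. A less mature liver in these mice may be a candidate explanation, but this test does not single it out. The labels give 8 to 12 weeks for all mice and no age per library, and the estimate is a hypothesis tested on the data that raised it. The medians of the Kupffer (0.23), stellate (0.14) and cholangiocyte (0.15) lists were above 0 and that of the endothelial list was -0.0169, so a higher share of other cells cannot be told apart from a change within them. Lists lower in HepKO and higher in HepWT replicate 2 could therefore reflect either difference. For the cell cycle list, a fall in HepKO was not seen apart from the replicate 2 libraries. Its direction reversed against HepWT replicate 1 alone and, by camera, with a block in HepWT only (adjusted p = 0.755).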
